A study of Mus musculus with 8 samples.

How the data were processed

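Total RNA from the prefrontal cortex of 8 male mice was hybridised to Affymetrix expression arrays, 1 array per mouse, after biotin labelling with the WT PLUS kit, per the labels' protocols. The mice were 12 weeks old, and the labels gave 4 as wild-type and 4 as Mll1 knockout. They had been housed singly for a week before the tissue was taken, so that fighting and handling would not add to gene expression, per the labels' protocols. The series' design text counted 4 mice per genotype, so the arrays of a group were taken as separate animals. A p-value for a single gene is judged against the spread between these 8 mice. Tests that set a group of genes against other genes use genes as units, so their p-values do not measure that spread.

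The values analysed were the authors' log2 signals of 35556 transcript clusters, each the summary of a set of probes along a gene. The tools named were Affymetrix Expression Console, RMA (background correction, quantile normalization of probes and a summary per cluster) and Transcriptome Analysis Console 3.0, per the submitters' processing notes, which give neither role nor order. Genome build, annotation release and array model were not given in the sources used here. For that reason no coordinates are printed, and the mouse reference gene table (assembly GRCm38.p6) served only for older symbols, for genomic span and for the order of neighbouring genes. The deposited log2 values had 2 decimals and a median between 7.99 and 8.08 on each array. Their spread was not the same on all arrays: the lower quartile lay at 6.89 to 6.94 on the wild-type arrays and 6.80 to 6.83 on the arrays labelled Mll1 knockout. No pair of arrays had equal values at more than 1339 clusters. Arrays give no count depth, and their number limits the precision.

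A further table held the authors' own comparison of 28944 of these clusters. Its columns were bi-weight mean log2 signals per genotype, a signed linear fold, an ANOVA p-value and an FDR p-value, per the file headers. The authors' fold was positive where wild-type was higher, so its sign is opposite to that of the differences given here. Recomputation showed that the authors' unadjusted p-value matched an unmoderated test per cluster, with 8154 clusters under 0.05 in both. Gene names came from this table, which gave 25400 clusters 1 gene symbol, 1436 clusters several genes and 2108 clusters none. The remaining 6612 clusters of the value table were outside it and were tested only as a whole.

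For each gene the cluster with the highest mean over all 8 arrays was used, which left 23983 genes, 730 of them with more than 1 cluster. No filter on dim genes and no further normalization was applied. Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the factor and no covariate, and are given as the arrays labelled Mll1 knockout minus wild-type. Adjusted p is from Benjamini-Hochberg over all 23983 genes, with a threshold of 0.05. For Kmt2a and for list means an exact two-sided permutation test was added, whose smallest p with 4 against 4 is 0.0286. For differences the error is the standard error (SE) from limma, and for levels it is the standard deviation (SD).

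Before the data were examined, 36 gene lists were fixed (chromatin complexes, synaptic and channel genes, markers of cortical and other cell types, stress and housekeeping pathways). Of their 948 entries 15 had no tested gene. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, stood beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. The rule for named genes was also fixed in advance. It took Kmt2a, the 15 largest rises and 15 largest falls among genes past the threshold whose 4 and 4 values did not overlap, and per list up to 4 passing members with the lowest p, or otherwise 2. Cell type lists added their 2 brightest members, and predicted genes, microRNA and snoRNA were not named. Some genes that the rule takes are counted in the totals but not reported here by name.

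Alternatives fixed in advance were quantile normalization of the deposited values, centring of each array, exclusion of dim genes, array weights, eBayes with trend and robust, an unmoderated test per gene, the mean of all clusters of a gene, the replicate number as a block, and each array left out in turn. Other thresholds, all clusters in place of genes and other list tests completed them. Cyclic loess normalization with 3 iterations, and leaving out wild-type arrays 1 and 4 together, were chosen after the data were seen.

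The procedure was tested on simulated data with the real gene means and spread, in which 200 of 23983 genes were changed. It recovered 40.3% of genes changed by 0.25 log2 and 100% of those changed by 0.5 or 1, with 10 false calls among 23783 unchanged genes. When the brightness trend of the real arrays was added, false calls numbered 345 without and 9 with quantile normalization. Recovery of changes of 0.25 log2 was then 59.7% without and 25.4% with it, so a call of that size that ended after quantile normalization can still be a real difference. All 50 simulated lists shifted by 0.15 log2 were recovered, and 1 of 249 unshifted lists was called, in data whose genes varied independently.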

Results

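The series profiled prefrontal cortex, dissected at the cingulate cortex, from 12-week-old male mice at rest. Arrays from 4 wild-type mice were compared with arrays from 4 mice labelled Mll1 knockout. Mll1, now named Kmt2a, is a histone methyltransferase that places methyl groups on lysine 4 of histone H3, a mark of active promoters. The values were RMA log2 signals, so a difference of 1 is a doubling. On each array 23983 genes were tested. The median signal lay between 7.99 and 8.08 on all arrays. The first principal component held 42.7% of the variance and separated the labelled genotypes. Wild-type replicate 1 lay farthest out at -20.33, the other wild-type arrays at -8.19 to -7.52 and the arrays labelled Mll1 knockout at 9.19 to 13.62. Wild-type replicate 4 stood apart on the second component, at -19.24.

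The targeted gene was examined first. Kmt2a (transcript cluster 10592942) was higher, not lower, on the arrays labelled Mll1 knockout. Its level was 10.06 ± 0.09 in wild-type and 10.35 ± 0.06 in the other group (SD, n = 4 and 4), with no overlap of the 4 and 4 values. The difference of 0.285 ± 0.0565 log2 (SE), or 1.22-fold, passed the threshold (limma, adjusted p = 0.0142), with an exact permutation p of 0.0286, the smallest this design allows. With wild-type arrays 1 and 4 both left out it was 0.222 and did not pass (limma, adjusted p = 0.0601). One cluster summarised probes along the gene, and the labels did not state which part was deleted, so this signal could come from outside the deleted part and does not check the labels. Groups are therefore named as labelled throughout, and every direction below rests on those labels.

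The main comparison asked which genes gave a different signal in prefrontal cortex on the arrays of the 2 labelled genotypes. The largest rise in signal was that of Rgs13 (10358399), a regulator of G protein signalling, from 6.06 ± 0.12 in wild-type to 7.76 ± 0.34 (SD, n = 4 and 4), a signal ratio of 3.25. That wild-type level lay under the lower quartile of each wild-type array (6.89 to 6.94) and was not tested against background, so the ratio of transcript levels is not known. The same holds for the wild-type levels of mt-Ty, Usp51 and S100a8 and, against lower quartiles of 6.80 to 6.83, for the levels of H60b, Il1rapl2, Cpa6 and Olfr180 on the arrays labelled Mll1 knockout. Glra3, a glycine receptor subunit, rose 2.40-fold and Cpne7, a calcium-dependent membrane-binding copine, rose 2.07-fold. The largest fall was that of Myl4 (10381798), a myosin light chain, from 10.57 ± 0.32 to 9.36 ± 0.12, which was 2.32-fold higher in wild-type.

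Among the 15 largest rises, all with non-overlapping values, were secreted and signalling proteins. Nov, a matricellular protein, rose by 0.90 ± 0.06 log2 (SE, adjusted p = 3.92e-05), and Tac1, the precursor of substance P, by 0.77 ± 0.12 (adjusted p = 0.0052). The serotonin receptor gene Htr2c rose by 0.69 ± 0.07 and Doc2b, a calcium sensor of vesicle release, by 0.69 ± 0.07. Scn7a, a sodium channel gene, rose by 0.71 ± 0.08. Enzyme genes in this group were Pcbd1, which acts in pterin recycling (0.87 ± 0.07), the kinase gene Cdkl4 (0.79 ± 0.05) and the deubiquitinase gene Usp51 (0.73 ± 0.09). The imprinted gene Nnat rose by 0.82 ± 0.12. The mitochondrial tRNA genes mt-Ty (0.83 ± 0.16) and mt-Ts1 (0.78 ± 0.11) and the gene AW551984 (0.76 ± 0.14) completed the 15.

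The 15 largest falls included genes of matrix and adhesion. Npnt, a matrix ligand of integrins, had a difference of -0.73 ± 0.06 log2 (SE, adjusted p = 0.000209). Adgrl2, an adhesion receptor of the latrophilin family, fell by 0.70 ± 0.06, and its 8 clusters gave -0.73 to -0.51. Abi3bp, a matrix protein gene, was at -0.67 ± 0.19 (adjusted p = 0.0431), with Mll1 knockout replicate 1 at 7.51 and the other 3 at 8.34 to 8.59. Without that array the difference was -0.425 (adjusted p = 0.0175). The call with all arrays ended under quantile normalization, although the difference stayed at -0.658 (adjusted p = 0.0741), and it ended without any 1 of 6 arrays (wild-type 1 to 4 or Mll1 knockout 3 or 4, adjusted p 0.0615 to 0.11). The homeobox gene Meis2 fell by 0.66 ± 0.07 and Arc, an activity-regulated gene of synapses, by 0.57 ± 0.09. The receptor genes Lgr5 (-0.71 ± 0.12) and Il1rapl2 (-0.69 ± 0.05), the peroxisomal transporter gene Abcd2 (-0.59 ± 0.06) and the secreted protein gene Dkk3 (-0.50 ± 0.06) fell as well. H60b (-0.73 ± 0.10), Nrep (-0.65 ± 0.06), Cpa6 (-0.65 ± 0.10) and the olfactory receptor gene Olfr180 (-0.50 ± 0.06) were also among the falls.

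**Figure D1:**
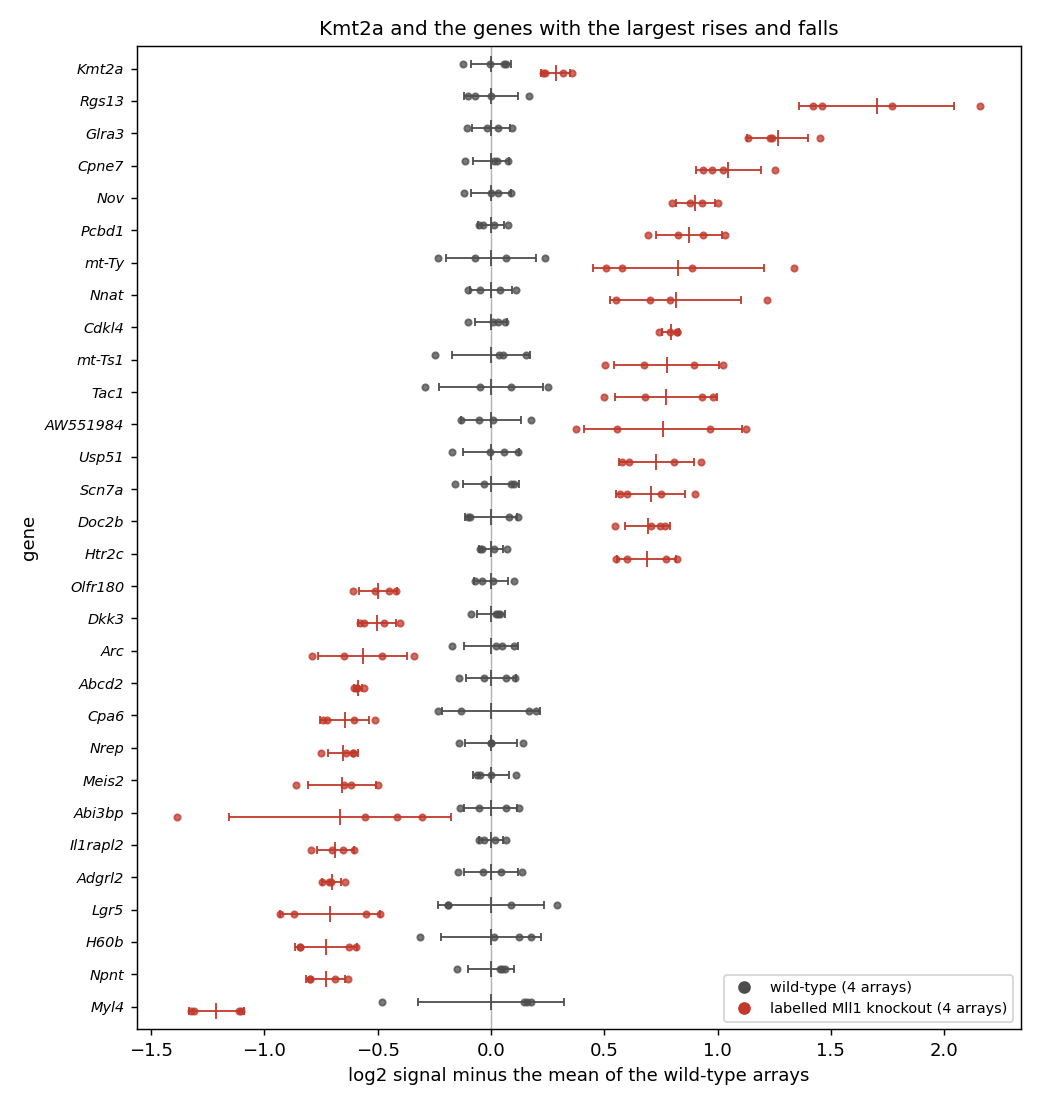
Log2 signal of Kmt2a and of the genes with the 15 largest rises and 14 of the 15 largest falls, drawn for each array as the difference from the wild-type mean. Points are arrays (grey, wild-type; red, labelled Mll1 knockout), and ticks with bars are the group mean and SD of 4 arrays; Rgs13 lies farthest to the right, at a mean of 1.70, and Myl4 farthest to the left, at -1.21.

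In all, 1236 genes were higher and 1364 lower on the arrays labelled Mll1 knockout (limma, adjusted p under the threshold of 0.05), so 47.5% of calls were rises. Most differences were small: 29 rises and 14 falls reached 1.5-fold, and 3 rises and 1 fall reached 2-fold. The split between rises and falls depended on the scaling. After quantile normalization 686 genes were higher and 379 lower, or 64.4% rises, and after cyclic loess 746 and 437, or 63.1%. The deposited and the quantile normalized values shared 591 rises and 295 falls, and no gene was called with opposite signs. The 15 largest rises and 14 of the 15 largest falls kept their calls, Abi3bp being the exception. With 1 array left out the rises numbered from 398 (without Mll1 knockout replicate 3) to 1506 (without wild-type replicate 4), and the falls from 313 to 1755 for the same arrays. The rises stayed within 1.5 times the full count only without wild-type replicate 3 or 4, and the falls only without these or Mll1 knockout replicate 4. The authors' deposited table gave 1194 clusters an FDR p-value under 0.05, and 705 of them were higher and 489 lower in the knockout.

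Dim genes and bright genes moved apart between the groups. Genes were divided by mean signal into 10 classes of equal size. In the second-dimmest class, from 6.12 to 6.91, genes had a median difference of -0.12 log2, and 241 of these 2398 genes fell while 13 rose. In the ninth class, from 9.70 to 10.47, the median was 0.068, and 268 genes rose while 54 fell. Over all genes the median was -0.032. After quantile normalization the medians of the 10 classes lay between -0.038 and 0.013. Where quantile normalization ended the call of a named gene, its adjusted p after it is given. The 34 such genes kept a median of 74.3% of their difference (49.1% to 100.7%), so an ended call does not by itself assign a difference to this shift.

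**Figure D2:**
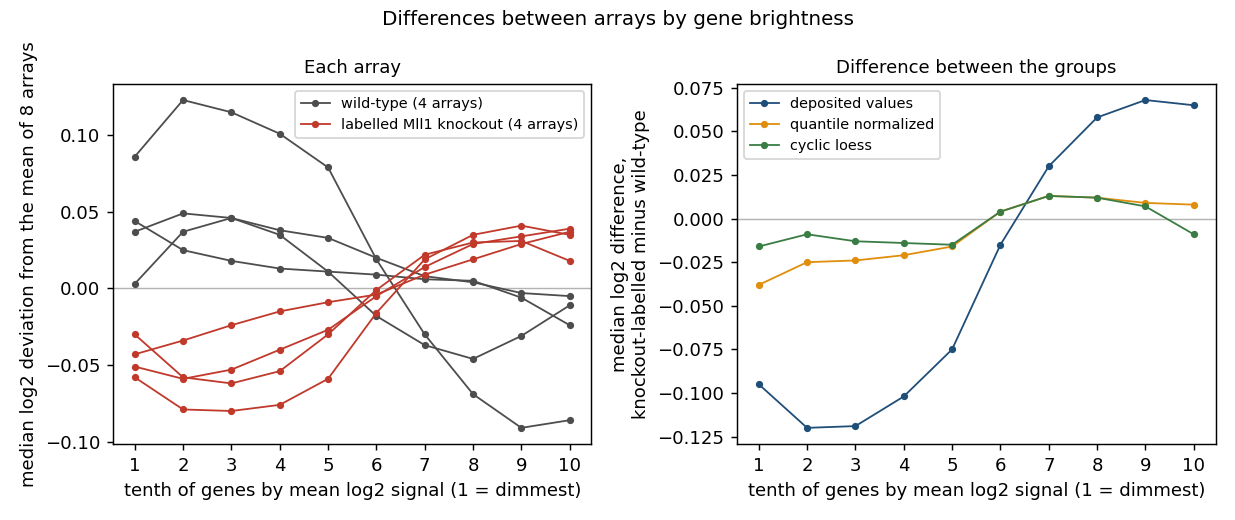
Median log2 deviation of genes in 10 classes of mean signal, from the dimmest (1) to the brightest (10): at left for each array against the mean of 8 arrays, at right for the arrays labelled Mll1 knockout minus wild-type, before and after further normalization. The difference between the groups runs from -0.12 in the second class to 0.068 in the ninth in the deposited values.

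Genes fixed in advance as linked to MLL1 in other tissues, mainly homeobox and blood stem cell factors, shifted downward. Of 22 members 4 fell over all genes tested (4 adjusted over the list alone) and none rose. They were Meis2, Satb1 (-0.44 ± 0.06 log2, SE), Mef2c (-0.31 ± 0.05) and Meis1 (-0.25 ± 0.06), and the Meis1 call ended after quantile normalization (adjusted p = 0.119). The list mean was -0.14 (camera adjusted p = 0.00864, and adjusted p = 0.236 with an estimated correlation). After quantile normalization it was -0.11 (camera adjusted p = 0.0119, and adjusted p = 0.264 with an estimated correlation). There 3 members passed, Meis2 (-0.705), Satb1 (-0.505) and Mef2c (-0.37). The Hoxa genes measured lay between -0.118 and -0.018 and did not pass, so a fall across the whole list is not shown. Among 16 TALE homeobox factors 3 fell and 1 rose over all genes (7 and 2 adjusted over the list alone). Mkx was at -0.39 ± 0.05, and Pbx2 rose by 0.29 ± 0.06. The TALE list did not pass (camera adjusted p = 0.423). Genes of H3K4 methyltransferase complexes shifted upward by a mean of 0.07 (camera adjusted p = 0.00638, and adjusted p = 0.357 with an estimated correlation). Of its 22 members 3 rose (4 adjusted over the list alone): Kmt2a, and the shared subunits Ash2l (0.20 ± 0.05) and Dpy30 (0.21 ± 0.05). The calls of the latter pair (adjusted p = 0.114 and 0.0973) and of the list (adjusted p = 0.25) ended after quantile normalization. None of 6 H3K4 demethylases passed by either count (camera adjusted p = 0.504), with Kdm5d at 0.09 ± 0.08 and Kdm5c at 0.03 ± 0.05.

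Synaptic genes changed in both directions. The lists in this paragraph had mean levels of 10.31 to 10.78, where many genes of any kind rose. In the brightest class, from 10.47, 334 of 2399 genes rose and 39 fell, and in the ninth 268 of 2398 rose and 54 fell. Among 37 synaptic adhesion molecules 9 rose and 2 fell over all genes tested (13 and 3 adjusted over the list alone). Lrrtm1 and Lrrtm3, postsynaptic partners of neurexins, rose by 0.43 ± 0.05 and 0.32 ± 0.05 log2 (SE), and Cadm3 by 0.32 ± 0.05, whereas Adgrl2 fell. Presynaptic release genes had 7 rises and 1 fall among 39 members (8 and 3 adjusted over the list alone), led by Doc2b and the vesicle protein gene Syngr3 (0.37 ± 0.05). Syn2 (0.29 ± 0.06) and Syt4 (0.22 ± 0.05) rose too, but their calls ended after quantile normalization (adjusted p = 0.0798 and 0.146). Ionotropic glutamate receptor genes had 4 rises and no falls among 29 members (4 and 0 adjusted over the list alone). These were the NMDA receptor subunit gene Grin3a (0.58 ± 0.08) and the AMPA receptor auxiliary genes Cnih3 (0.35 ± 0.07), Cacng8 (0.22 ± 0.05) and Shisa6 (0.17 ± 0.05), of which Cacng8 lost its call after quantile normalization (adjusted p = 0.0622).

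These 3 lists shifted upward in the deposited values. Camera adjusted p was 0.000159 for adhesion molecules, 0.00892 for release genes and 0.00499 for glutamate receptors, with means of 0.085, 0.052 and 0.075, that of release genes being 0.034 without wild-type replicate 1. All 3 calls were lost with an estimated correlation (adjusted p = 0.357, 0.648 and 0.368 with an estimated correlation). They also ended after quantile normalization (adjusted p = 0.0983, 0.989 and 0.288), and after cyclic loess the presynaptic release machinery lay slightly below the other genes, at -0.01. Without wild-type arrays 1 and 4 the release genes did not pass either (adjusted p = 0.201). Postsynaptic density scaffolds and plasticity kinases had 2 rises and 2 falls among 35 members by either count. Camk2d rose by 0.48 ± 0.07 and Tiam1 by 0.21 ± 0.05, while Camk2g (-0.24 ± 0.05) and Camk4 (-0.24 ± 0.07) fell. The Tiam1 call ended after quantile normalization (adjusted p = 0.109). The list did not pass in the deposited values (mean 0.003, median 0, camera adjusted p = 0.504), and passed in the downward direction after quantile normalization (mean -0.051, adjusted p = 0.0277, and adjusted p = 0.442 with an estimated correlation).

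Among 19 GABA receptor genes Gabra2 rose (0.43 ± 0.09 log2, SE) and Gabrg3 fell (-0.25 ± 0.06), with 2 rises and 1 fall adjusted over the list alone. The Gabra2 call ended after quantile normalization (adjusted p = 0.0588). The list did not pass in the deposited values (camera adjusted p = 0.947) and shifted downward after quantile normalization (mean -0.042, adjusted p = 0.0304, and adjusted p = 0.264 with an estimated correlation). Of 7 metabotropic glutamate receptor genes Grm5 rose (0.19 ± 0.06) and Grm2 fell (-0.20 ± 0.05), with 1 rise and 2 falls adjusted over the list alone (camera adjusted p = 0.793). The Grm5 call ended after quantile normalization (adjusted p = 0.213). Among 36 monoamine and acetylcholine receptor genes 2 rose and 4 fell (5 and 6 adjusted over the list alone). Htr2c and Htr1a (0.36 ± 0.05) rose, while the dopamine receptor gene Drd5 (-0.45 ± 0.06) and the adrenergic receptor gene Adra1a (-0.36 ± 0.05) fell. The list had a negative mean and median, at -0.010 and -0.031, and an upward camera direction that did not pass (adjusted p = 0.889).

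Among 56 potassium channel genes 5 rose and 8 fell (6 and 10 adjusted over the list alone). Kcnd3 (0.35 ± 0.05), Kcnf1 (0.37 ± 0.05) and Kcng1 (0.40 ± 0.08) rose and Kcnh7 fell (-0.43 ± 0.06). The list did not pass in the deposited values (camera adjusted p = 0.666) but shifted downward after quantile normalization, with a mean of -0.067 (adjusted p = 0.0007, and adjusted p = 0.264 with an estimated correlation). Of 32 sodium, calcium and HCN channel genes 3 rose and 3 fell (3 and 4 adjusted over the list alone). Scn7a, Scn3b (0.55 ± 0.05) and Cacna1h (0.26 ± 0.05) rose and Ryr1 fell (-0.26 ± 0.04); the list did not pass (mean 0.011, median 0, camera adjusted p = 0.547). Neuropeptide genes had 5 rises and 1 fall among 44 members (8 and 2 adjusted over the list alone). Tac1 and the receptor genes Npy1r (0.51 ± 0.09) and Adcyap1r1 (0.23 ± 0.06) rose and Hcrtr2 fell (-0.25 ± 0.06), and the calls of Adcyap1r1 and Hcrtr2 ended after quantile normalization (adjusted p = 0.0769 and 0.171). The neuropeptide list did not pass with all arrays (camera adjusted p = 0.0616, and adjusted p = 0.34 with an estimated correlation) and passed upward without wild-type replicate 1 (adjusted p = 0.019) or Mll1 knockout replicate 3 (adjusted p = 0.0391). None of 22 clustered protocadherin genes of the beta cluster passed by either count (camera adjusted p = 0.504), and Pcdhb6 was at -0.20 ± 0.06 and Pcdhb1 at -0.19 ± 0.07.

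Markers of cortical neuron classes split within each list. Of 25 upper layer excitatory neuron markers 3 rose and 5 fell (6 and 7 adjusted over the list alone), with Mef2c and Rspo1 (-0.39 ± 0.05 log2, SE) among the falls and the semaphorin receptor gene Plxnd1 among the rises (0.34 ± 0.05). Of 31 deep layer markers 5 rose and 8 fell (7 and 10 adjusted over the list alone). The transcription factor genes Foxp2 (-0.48 ± 0.06) and Tbr1 (-0.46 ± 0.06) fell, while Crym (0.51 ± 0.07) and Ctgf (0.49 ± 0.06) rose with Htr2c. Neither list passed (camera adjusted p = 0.793 and 0.342), although the upper layer list shifted downward when dim genes were left out (adjusted p = 0.0397, against 0.944 with an estimated correlation and all genes). GABAergic interneuron markers had 1 rise, Tac1, and 5 falls among 33 members by either count. Reln, an extracellular protein (-0.42 ± 0.06), and the transcription factor genes Dlx1 (-0.41 ± 0.06) and Sp8 (-0.35 ± 0.05) fell. The bright marker Sst (0.21 ± 0.08) did not pass. That list had a mean of -0.08 (camera adjusted p = 0.0521, and adjusted p = 0.236 with an estimated correlation). It passed after quantile normalization, with a mean of -0.09 (adjusted p = 0.0016, and adjusted p = 0.264 with an estimated correlation). Without wild-type replicate 1, Mll1 knockout replicate 1 or Mll1 knockout replicate 2 it also passed (adjusted p = 0.0428, 0.0363 and 0.0394). Striatal neuron markers had 2 rises and 2 falls among 22 members by either count: Tac1 and Pde1b (0.21 ± 0.06) rose, and Adora2a (-0.41 ± 0.07) and Foxp1 (-0.31 ± 0.05) fell. The Pde1b call ended after quantile normalization (adjusted p = 0.112), the bright markers Penk (0.22 ± 0.08) and Arpp21 (0.13 ± 0.05) did not pass, and the list did not either (camera adjusted p = 0.312).

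Immediate early genes went both ways, with 3 rises and 6 falls among 40 members (3 and 8 adjusted over the list alone). Arc fell, while Ptgs2 (0.54 ± 0.09 log2, SE), Jun (0.48 ± 0.06) and Jund (0.22 ± 0.05) rose, and the Jund call ended after quantile normalization (adjusted p = 0.0967). The list did not pass with all genes (mean -0.063, or -0.034 without Mll1 knockout replicate 2, camera adjusted p = 0.423) and shifted downward when dim genes were left out (adjusted p = 0.00137 at the preset correlation, against 0.92 with an estimated correlation and all genes).

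Microglia markers had a mean of 0.096 (camera adjusted p = 0.00117, and adjusted p = 0.629 with an estimated correlation), with 2 rises among 22 members by either count: Cd68 (0.27 ± 0.07 log2, SE) and Ly86 (0.24 ± 0.07), of which Ly86 lost its call after quantile normalization (adjusted p = 0.12). The bright marker C1qb (0.15 ± 0.07) did not pass. In the deposited values the array means of the microglia list met between the groups, at 0.0016 for wild-type replicate 2 and Mll1 knockout replicate 2. They lay farthest apart for wild-type replicate 4 (-0.122) and Mll1 knockout replicate 4 (0.14), and the exact permutation p was 0.0571. The microglia list kept its call after quantile normalization (camera adjusted p = 0.00719, and adjusted p = 0.675 with an estimated correlation). It missed the threshold when dim genes were left out (adjusted p = 0.0752). Oligodendrocyte precursor markers had a mean of 0.075 (camera adjusted p = 0.0176, and adjusted p = 0.314 with an estimated correlation). Of its 12 members Pdgfra (0.22 ± 0.04) and Tnr (0.24 ± 0.05) rose over all genes (5 rises and 1 fall adjusted over the list alone), and both calls ended after quantile normalization (adjusted p = 0.0511 and 0.0519). The list's own call ended too (adjusted p = 0.163), and likewise without Mll1 knockout replicate 2 (adjusted p = 0.0548) or without wild-type arrays 1 and 4 (adjusted p = 0.0505). Astrocyte markers had a mean of 0.053 and no member of 22 past the threshold by either count (camera adjusted p = 0.0382, and adjusted p = 0.34 with an estimated correlation). Aldoc (0.14 ± 0.04), Cldn10 (0.23 ± 0.07) and Slc1a2 (-0.03 ± 0.04) were among these. That call ended after quantile normalization (adjusted p = 0.919) and without wild-type replicate 1 or 2 or Mll1 knockout replicate 2, 3 or 4 (adjusted p 0.0534 to 0.063).

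Oligodendrocyte markers had a mean of -0.093, with 1 fall among 23 members by either count, that of Enpp2 (-0.46 ± 0.07). Mbp (-0.0025 ± 0.0511) did not pass. The list missed the threshold in the deposited values (camera adjusted p = 0.0651, and adjusted p = 0.82 with an estimated correlation) and passed without wild-type replicate 1 (adjusted p = 0.0123) or Mll1 knockout replicate 2 (adjusted p = 0.00284). After quantile normalization its mean was -0.12 (adjusted p = 0.00036, and adjusted p = 0.442 with an estimated correlation). Blood cell markers had a mean of -0.20 (camera adjusted p = 0.0105, and adjusted p = 0.236 with an estimated correlation). Of 8 members 3 fell (7 falls and 1 rise adjusted over the list alone): S100a8 (-0.26 ± 0.05), Alas2 (-0.22 ± 0.05) and S100a9 (-0.20 ± 0.05). None of the 8 passed after quantile normalization (limma, adjusted p = 0.064 for S100a8, 0.123 for Alas2 and 0.267 for S100a9). The list did pass after it (camera adjusted p = 0.0173, and adjusted p = 0.264 with an estimated correlation). The haemoglobin gene Hba-a1 was at -0.39 ± 0.12. Choroid plexus and ependyma markers had 3 falls among 15 members (6 adjusted over the list alone), led by Slc4a5 (-0.25 ± 0.05). None of these remained after quantile normalization (limma, adjusted p = 0.0796 for Slc4a5). Among the fits run the list passed only without wild-type replicate 3 (camera adjusted p = 0.0245) or Mll1 knockout replicate 4 (adjusted p = 0.0216). With all arrays its camera adjusted p was 0.0652 (0.799 with an estimated correlation). Endothelial and mural cell markers (0 of 24 members by either count, camera adjusted p = 0.457, or 0.92 with an estimated correlation, and 0.0328 downward when dim genes were left out) had Vwf at -0.16 ± 0.05 and Ly6c1 at -0.06 ± 0.11. Meninges and fibroblast markers (1 rise of 16 by either count, that of Pdgfra, camera adjusted p = 0.889) had Ptgds at -0.09 ± 0.09.

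Ribosomal protein genes gave the largest mean shift of the 36 lists fixed in advance. Of 44 members 32 rose over all genes tested (38 adjusted over the list alone) and none fell, with a mean of 0.25 log2 and list means of the 4 and 4 arrays that did not overlap. Rpl8 rose by 0.47 ± 0.07 (SE), Rps24 by 0.40 ± 0.05, Rpl37 by 0.36 ± 0.05 and Rps7 by 0.33 ± 0.05. The list passed in the deposited values (camera adjusted p = 2.15e-23, and adjusted p = 0.236 with an estimated correlation). After quantile normalization 9 members rose and the mean was 0.20 (adjusted p = 4.15e-18, and adjusted p = 0.274 with an estimated correlation). Mitochondrial respiratory chain genes had 4 rises among 47 members by either count, with a mean of 0.12 (camera adjusted p = 8.95e-10, and adjusted p = 0.236 with an estimated correlation). Cox7a2 rose by 0.38 ± 0.06. Cyc1 (0.26 ± 0.06), Ndufb8 (0.22 ± 0.06) and Uqcrh (0.23 ± 0.06) lost their calls after quantile normalization (adjusted p = 0.0916, 0.0977 and 0.201), and the list kept its own at the preset correlation (mean 0.068, adjusted p = 0.00167) but not with an estimated correlation (adjusted p = 0.543).

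Heat shock and unfolded protein response genes had a mean of 0.072 (camera adjusted p = 0.00537, and adjusted p = 0.236 with an estimated correlation). Its 2 rises among 22 members by either count were Dnajb1 (0.20 ± 0.05 log2, SE) and Hspa1a (0.20 ± 0.06). All 3 calls ended after quantile normalization (adjusted p = 0.227 for the list, 0.115 for Dnajb1 and 0.057 for Hspa1a, whose difference stayed at 0.1988). Glucocorticoid and stress genes had 2 rises, Fkbp5 (0.36 ± 0.09) and Mt1 (0.23 ± 0.05), and 1 fall, the glucocorticoid receptor gene Nr3c1 (-0.22 ± 0.06), among 19 members by either count. The list did not pass with all arrays (camera adjusted p = 0.121, and adjusted p = 0.862 with an estimated correlation) and passed upward without Mll1 knockout replicate 1 (adjusted p = 0.0363) or 4 (adjusted p = 0.0155) and with array weights (adjusted p = 0.0479), and the Mt1 call ended after quantile normalization (adjusted p = 0.0795). Of 19 circadian clock genes 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.143). Rorb was at -0.31 ± 0.08, while Bhlhe41 (0.28 ± 0.08, or 0.188 without wild-type replicate 1) and Csnk1d (0.16 ± 0.04) lost their calls after quantile normalization (adjusted p = 0.102 and 0.216). Among 22 DNA damage and p53 target genes Plk2 alone rose, by 0.33 ± 0.07 (1 adjusted over the list alone, camera adjusted p = 0.947).

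Of 27 innate immune and interferon response genes 3 fell by either count: Tnf (-0.32 ± 0.06), Usp18 (-0.26 ± 0.07) and Ifih1 (-0.19 ± 0.04). The calls of Usp18 and Ifih1 ended after quantile normalization (adjusted p = 0.141 and 0.233), and the list did not pass (camera adjusted p = 0.423). Among 18 retinoic acid pathway genes the enzyme gene Aldh1a1 fell (-0.49 ± 0.06) and the carrier gene Rbp4 rose (0.24 ± 0.06) by either count, and Rbp4 lost its call after quantile normalization (adjusted p = 0.0836). That list did not pass either (camera adjusted p = 0.889).

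**Figure D3:**
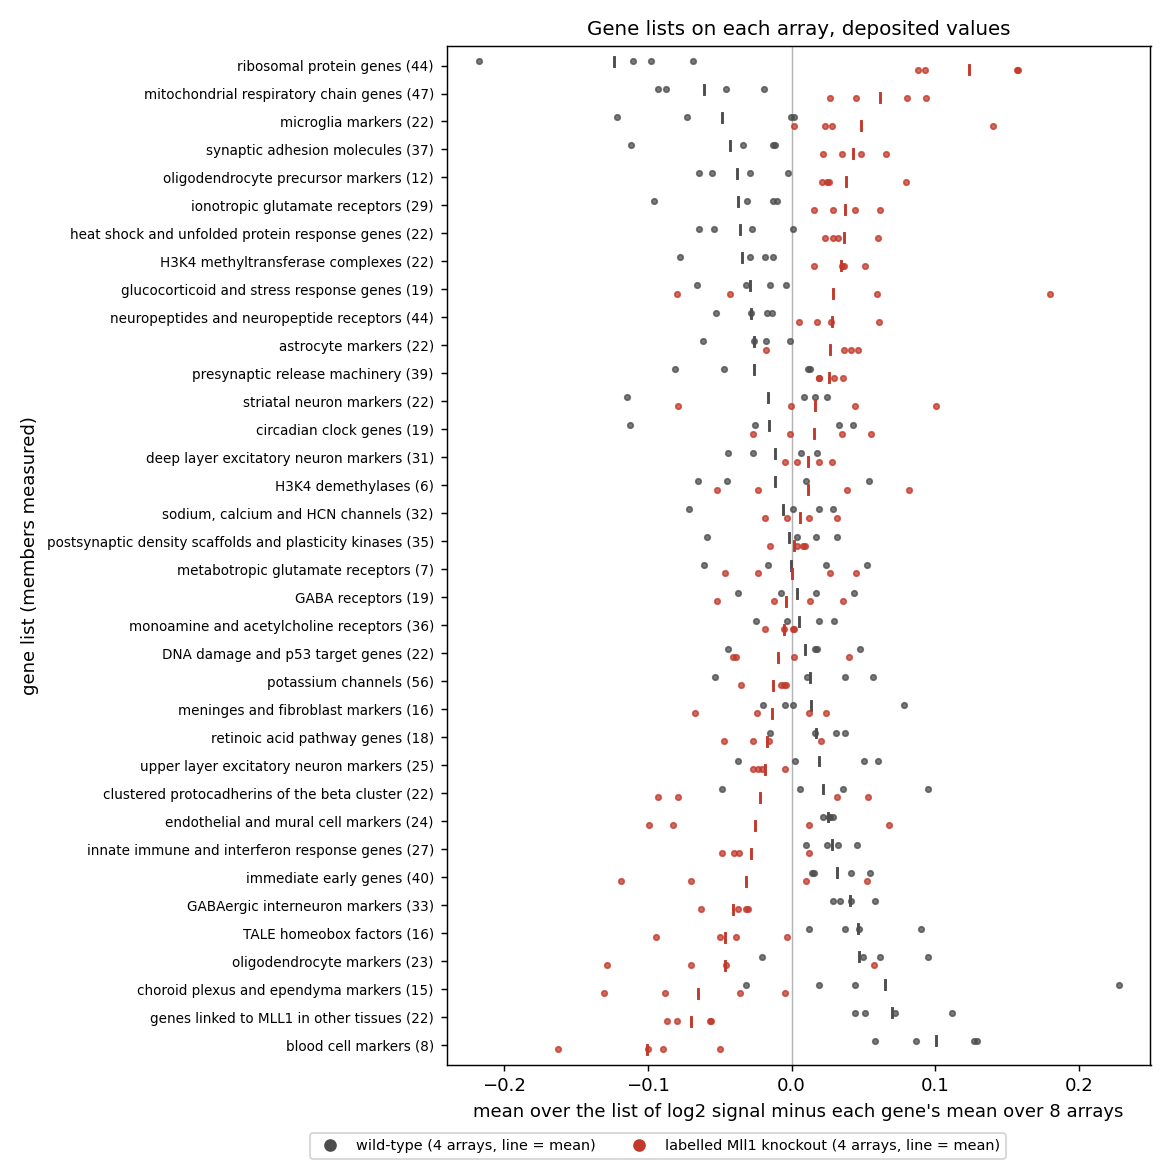
Mean of each of the 36 gene lists on each array, as log2 signal minus each gene's mean over 8 arrays, in the deposited values. Points are arrays (grey, wild-type; red, labelled Mll1 knockout), short lines are group means of 4 arrays; ribosomal protein genes differ most upward (0.25) and blood cell markers most downward (-0.20).

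In total 12 of the 36 lists passed with the preset correlation, and 0 with an estimated correlation, where the smallest adjusted p was 0.236. By fry 10 lists moved on balance in one direction, which does not set them against other genes. Among these were GABAergic interneuron markers (fry adjusted p = 0.000831) and innate immune and interferon response genes (0.0346), which camera did not call with all arrays. Presynaptic release genes (0.104), ionotropic glutamate receptors (0.0528), astrocyte markers (0.0824) and microglia markers (0.162) passed by camera but not by fry. Splitting the 8 arrays into 4 and 4 in other ways gave up to 14 passing lists with the preset correlation, so the number of lists is not larger than other groupings gave. Of the 117 named genes past the threshold, 83 kept their call after quantile normalization and 75 whichever array was left out. Some that passed after quantile normalization lost the call in most of the 8 fits with 1 array left out. Camk4 kept it in 1 of these fits, Nr3c1 and Shisa6 in 2, and Grm2, Cd68 and Rorb in 3.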

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

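The counts over transcript clusters outside the gene comparison were chosen after the data were seen, and the test for outlying arrays before. In each group of 4 arrays the gap between the outermost array and its nearest neighbour was divided by the group's range, and arrays above Dixon's critical value for 4 were singled out as far from the others. This was done for 372 groups, the named genes and the lists in both genotypes, of which 25 were singled out against 18.6 expected, since chance singles out about 1 in 20. Wild-type replicate 1 was the outlying array in 8 of them and wild-type replicate 4 in 5.

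Wild-type replicate 1 was lowest for Dkk3 (10.73 against 10.84 to 10.86, a gap of 0.846 of the range), Cnih3 (10.12 against 10.38 to 10.42, 0.867), Htr1a (8.64 against 8.76 to 8.78, 0.857) and Foxp1 (10.22 against 10.34 to 10.36, 0.857). It was also lowest for Bhlhe41 (8.52 against 8.89 to 8.91, 0.949) and Aldh1a1 (9.43 against 9.54 to 9.55, 0.917), and highest for Slc4a1 (8.54 against 8.33 to 8.36, 0.857). Its mean over striatal neuron markers was -0.114 against 0.009 to 0.024 on the other wild-type arrays (0.889). Wild-type replicate 4 was lowest for Myl4 (10.09 against 10.72 to 10.75, 0.955), Npnt (8.75 against 8.94 to 8.96, 0.905), Kcng1 (9.75 against 10.09 to 10.13, 0.895) and Sst (11.74 against 12.01 to 12.03, 0.931), and highest for Scn3b (10.91 against 10.78 to 10.79, 0.923). Wild-type replicate 3 was highest for Mkx (9.21 against 9.13 to 9.14, 0.875) and lowest for Ryr1 (8.60 against 8.62 on each of the others, the whole range, 1).

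Among the arrays labelled Mll1 knockout, replicate 3 was highest for Camk2g (10.95 against 10.86 to 10.87, 0.889) and Aldoc (13.17 against 13.11 to 13.12, 0.833) and lowest for Kcng1 (10.35 against 10.43 to 10.44, 0.889). Replicate 4 was highest for Cadm3 (11.45 against 11.26 to 11.28, 0.895) and C1qb (10.28 against 10.01 to 10.05, 0.852), and lowest for Kcnf1 (10.24 against 10.29 to 10.30, 0.833) and Sst (11.97 against 12.20 to 12.24, 0.852). Its mean over potassium channels was -0.035 against -0.007 to -0.004 (0.902). Replicate 1 had the lowest mean over astrocyte markers (-0.018 against 0.036 to 0.046, 0.851), and replicate 2 the highest over oligodendrocyte precursor markers (0.079 against 0.021 to 0.026, 0.914).

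Outside the genes tested, 56 of 2108 transcript clusters without a gene symbol passed the threshold (limma, Benjamini-Hochberg over these clusters), 33 higher and 23 lower on the arrays labelled Mll1 knockout. They are a signal in data that the comparisons of the report do not use, and 569 (27%) had an unadjusted p under 0.05. Another 6612 clusters had values but no entry among the authors' deposited results. Limma called 0 of them, with 694 (10.5%) at an unadjusted p under 0.05.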

How the results depend on the processing

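Cyclic loess normalization and leaving out wild-type arrays 1 and 4 together were chosen after the data were seen, and the other settings before the data were examined. The counts of rises and falls, 1236 and 1364, moved with the scaling. They were 686 and 379 after quantile normalization, 746 and 437 after cyclic loess, and 2845 and 482 with each array centred on its median. With dim genes left out 1514 rises and 463 falls were called, with fewer genes tested, and array weights gave 1695 and 2469. An unmoderated test per gene gave 552 and 384, an adjusted p under 0.10 gave 2237 and 3263, and an unadjusted p under 0.05 with a 1.5-fold difference gave 31 and 16. Without wild-type arrays 1 and 4 the counts were 424 and 395, and with 1 array left out 398 to 1506 rises and 313 to 1755 falls, where fewer arrays were fitted. Rises and falls both moved by more than 1.5 times without wild-type replicate 1 (586 and 478) or 2 (788 and 657), or Mll1 knockout replicate 1 (667 and 498), 2 (505 and 362) or 3 (398 and 313). Rises alone did without Mll1 knockout replicate 4 (724). The Kmt2a difference kept its direction in every setting run, with a range of 0.22 to 0.346, and lost its call only without wild-type arrays 1 and 4 (0.222, adjusted p = 0.0601). The count of 12 lists became 0 by camera with an estimated correlation (6 at an unadjusted p under 0.05) and 10 by fry or after quantile normalization, and was 11 to 14 with 1 array left out. Relative to the other genes, the list of postsynaptic density scaffolds and plasticity kinases turned from 0.027 to -0.049 after quantile normalization and -0.064 after cyclic loess, and presynaptic release machinery from 0.076 to -0.01 after cyclic loess. Apart from the number of genes or arrays fitted, the cause of these changes was not tested. No named gene past the threshold changed direction in any setting run. Of the 117 that passed, 34 lost the call after quantile normalization and 42 without at least 1 array, while 75 kept it whichever array was left out. No pairing by the replicate numbers shared by the genotypes was seen. Correlations of same-numbered arrays' deviations were -0.008, 0.01, 0.002 and 0.024, and the highest with another number were 0.133 to 0.158. Each of the latter is the highest of several values, so a pairing of the mice is not excluded. With the replicate block 799 genes were higher and 759 lower. Signal near the background limits dim genes, whose differences followed the shift between dim and bright genes.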

Other observations

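The gene groups in this part, and the tests of explanations other than those of genomic span, single arrays and other splits of the arrays, were chosen after the results were seen. Camera adjusted p for these groups covers only the groups so chosen. A pass therefore describes a group picked from the same data and is no independent support. Genes of the Bex and Tceal families, small adaptor proteins of neurons, were higher on the arrays labelled Mll1 knockout, with 6 of 9 members past the threshold (limma) and none lower. Bex1 was up by 0.617 ± 0.096 log2 (SE) and Tceal6 by 0.545 ± 0.114, and the mean was 0.288, and 0.291 after quantile normalization. The group passed against other genes with an estimated correlation (camera adjusted p = 0.0284). Of 10 glutathione S-transferase genes of the alpha and mu classes, which conjugate glutathione to reactive compounds, 5 rose, among them Gsta4 (0.63 ± 0.068), Gstm7 (0.428 ± 0.055) and Gstm6 (0.423 ± 0.072). Their mean was 0.194, and 0.201 after quantile normalization, but the call ended with an estimated correlation (adjusted p = 0.14).

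Zinc finger genes with Zfp symbols, largely DNA-binding repressors, had 23 rises and 6 falls among 346 members, and 22 and 2 after quantile normalization. Over all 23983 genes the counts were 1236 and 1364, and 686 and 379 after quantile normalization. Zfp455 (0.46 log2, adjusted p = 0.00312) and Zfp763 (0.463, adjusted p = 0.0172) rose with Zfp758 (0.433, adjusted p = 0.036) and passed both ways, and Zfp385b (-0.22) and Zfp385c (-0.25) fell. The list passed with an estimated correlation only after quantile normalization (camera adjusted p = 0.0495, against 0.0894 in the deposited values). Of 43 snoRNA genes 7 rose and none fell, and 6 rose after quantile normalization (camera adjusted p = 0.0444 with an estimated correlation). Of 17 mitochondrial tRNA genes 4 rose, mt-Ty, mt-Ts1, mt-Tn (0.595 ± 0.133) and mt-Te (0.37 ± 0.103), the last losing its call after quantile normalization (adjusted p = 0.0811). Zfp455 (mean level 6.26), Zfp758 (6.74) and mt-Tn (5.63) lay under the lower quartile of every array and were not tested against background, so their transcript ratios are not known. As a list the tRNA genes did not pass with an estimated correlation (camera adjusted p = 0.175). Among 17 imprinted genes Nnat and Ndn (0.613 ± 0.125) rose and kept the call after quantile normalization. Grb10 (0.168) and Usp29 (0.183) rose and H19 fell (-0.18 ± 0.052), and these 3 calls ended after it, while Peg3 was at 0 ± 0.054. Of 44 collagen genes 8 fell and none rose, but all 8 calls ended after quantile normalization, where the mean was still -0.105. Among 58 histone genes with Hist symbols 1 rose and 1 fell, and the fall did not pass after quantile normalization. The 100 nearest annotated neighbours of Kmt2a held 12 called genes, or 12.0% against 10.8% elsewhere (Fisher's exact test, two-sided, p = 0.631).

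Dim genes were lower and bright genes higher on the arrays labelled Mll1 knockout. A background or distribution difference between the arrays was examined on 1398 olfactory and vomeronasal receptor genes, which cortex largely does not use. Their median was -0.137 log2 (95% interval from resampled genes, not mice, -0.142 to -0.132). Such a difference would give this, but these genes are themselves dim, and dim genes had already been seen to fall. The value therefore restates the pattern and does not decide on its cause. After quantile normalization the median was -0.063 (exact permutation p = 0.0857 for the list mean). A fall in transcription of weakly expressed genes remains open: other genes of the same brightness lay 0.038 above the receptor genes (0.030 to 0.046), but signals this near the background decide nothing. A difference of genotype stays open as well and was not tested.

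Ribosomal protein genes were higher on the arrays labelled Mll1 knockout. Their mean exceeded that of 10000 random lists matched on brightness by 0.192 log2 (random lists 0.018 to 0.094, 0 as high), and that of lists matched on brightness and genomic span by 0.163 (0.044 to 0.122). The size of these gaps argues against either as the whole cause. The random lists were drawn gene by gene, so their ranges are too narrow for genes that vary together. The count of 0 as high therefore does not measure evidence across mice. A single array out of line is argued against too, since the smallest mean with 1 array left out was 0.216. Of 114 ribosomal protein pseudogenes 59 also rose, and 29 after quantile normalization (camera adjusted p with an estimated correlation 0.0284 and 0.0734), and probes shared between genes and pseudogenes were not examined here. RNA quality and a difference of genotype were not tested and stay open.

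The transcription factor genes Tbr1, Fezf2, Bcl11b, Foxp2, Satb1 and Meis2, which shape cortical projection neurons, had a median of -0.447 log2 (-0.57 to -0.26). They were picked because they fell, while others of the layer lists, such as Cux1 (0.0175), Tle4 (0.01), Etv1 (0.115) and Bcl6 (0.145), did not pass, so no fall of the whole class is shown. After quantile normalization 6 of the 6 were still lower and past the threshold (median -0.493, -0.61 to -0.316), and likewise after cyclic loess. Genes of their brightness (mean levels 8.7 to 11.14) shifted upward, with class medians of 0.03 to 0.068. Removing that shift could hardly end their calls, so these fits are no separate test. Its upward direction argues against the brightness-dependent shift as the whole cause of these falls. A lower share of excitatory neurons in general would lower their abundant genes by about as much. The 9 excitatory genes had a median of -0.018 (-0.057 to 0.133), with Neurod2 lower (-0.192, limma, adjusted p = 0.0474). Less striatum in the dissections would lower striatal genes, but how much of the factors' signal came from striatum was not measured. The 8 striatal genes had a median of -0.071 (-0.203 to 0.098), with Adora2a lower (-0.41). After quantile normalization the medians were -0.062 (-0.116 to 0.09) and -0.133 (-0.263 to 0.034). Both intervals lay above that of the factors, a bound reset after these values were seen. The first, stricter one was narrowly missed by the striatal genes after quantile normalization. Because the factors were picked for their fall, their interval is low by choice, and the striatal genes cleared it narrowly, so less striatum stays open. The excitatory medians argue only against a lower share of excitatory neurons in general as the whole cause. A lower share of some classes of these neurons and a difference of genotype were not tested and stay open.

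Of the 35 splits of the 8 arrays into 4 and 4, only 1, the labelled one, gave as many as 2600 called genes by limma, and the highest other gave 0. After quantile normalization the labelled split gave 1065, again 1 of 35, and the highest other 0. This argues against chance for the number of genes but does not exclude it. A share of 1 of 35 is the smallest possible, and every other split mixes the labelled groups. For the number of lists chance stays open: 6 of 35 splits gave at least the 12 of the labelled split, and the highest other gave 14. Nor do the splits separate genotype from how the arrays were processed. A batch could coincide with the labels, which give no scan date or batch, and none was tested.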
